A study of Mus musculus with 51 samples.

How the data were processed

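Cells were sorted by flow cytometry from mammary glands of WT, D542G and Y541S mice at 6 months of age, after hormone pellets and 4 daily doses of vehicle or giredestrant. Per the labels' protocols, RNA was purified with a Qiagen micro kit and libraries were made from cDNA with Nextera XT. The 51 libraries formed 17 groups of 3, named by genotype, treatment and sorted population. The population came from the sample titles and the cell type labels, which were identical in all 51 libraries. The source name calls every sample mature luminal cells and was therefore not used. The N gate and its surface markers are not given in the sources used here.

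Each library came with 1 table of genes. The values tested were raw counts per gene, deposited by the authors as whole numbers in the count column, with no scaling per the file headers. The deposited RPKM values, so called per the file headers, were recomputed as counts over gene width and a library total. That total was recovered from them (24.6 to 68.3 M, largest relative deviation 9.7e-13), and the summed counts made up 85.0 to 89.1% of it. RPKM values entered no test. The build was GRCm38, per the submitters' processing notes. The aligner, the counting tool and the annotation are not given in the sources used here.

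Of 52636 genes in the tables, 52489 were named by their identifiers in GENCODE M21, and 80 symbols were shared by more than 1 gene. For 44954 genes (85.6%) the width column equalled the span of the gene with its introns. Protein-coding genes that lie wholly inside the spans of others had a count of 0 in every library in 88.9% of cases (1124 of 1264), against 16.2% (1960 of 12082) where no other gene overlaps. With other genes on the opposite strand alone the share was 88.3% (640 of 725). This is the pattern left when reads in shared spans of either strand are not counted. Levels of genes overlapped over at least 50% of their span, such as Tagln, Tnc, Cxcl10 and Elf3, are therefore uncertain. Close paralogs such as Krt6a and Krt6b, the Klk1 family and Saa1 and Saa3 share sequence, and how their reads were assigned is not given in the sources used here.

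Total counts per library were 21.4 to 60.1 M (median 32.9). Between libraries of 1 group the counts varied far more than counting error, with a chi-square per degree of freedom of 23.73 to 308.51, so the tests use the spread between samples rather than counting error. Genes with few counts are also limited by depth. No 2 libraries of a group were duplicates by this measure.

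Differences were tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood F test, with TMM scaling and its default filter by group on low counts. Libraries were fitted together by panel, 18 of ML (17181 genes), 18 of Basal (17173), 9 of LP (16569) and 24 of the mutants with giredestrant (18247, for all comparisons of N). Each group had its own mean. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of its comparison. The 24 comparisons were giredestrant against vehicle per genotype, each mutant against WT per treatment, the difference of giredestrant effects between each mutant and WT, N against each other population (average of both mutants) and N between mutants. CPM were computed with TMM factors over all 51 libraries. A ± after a CPM value is the SD of the libraries, and after a log2 ratio its SE, the ratio divided by the square root of F. Fold changes in the text are such log2 ratios.

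There were 22 gene lists, and a list needed 3 members in a fit. They covered estrogen and progesterone receptor targets, proliferation, markers of mature luminal, luminal progenitor, milk and alveolar, basal and pan-luminal cells, epithelial to mesenchymal transition, squamous genes, markers of fibroblasts, endothelium, pericytes, immune cells, adipocytes and skeletal muscle, interferon response, immediate early and heat shock genes, cholesterol synthesis, and the Notch, Wnt and epidermal growth factor receptor pathways. Lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the lists of a comparison. Counts of called members are from edgeR.

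Signatures of ML, LP and Basal were the genes called higher in 1 population than in each of the other 2 in WT with giredestrant, up to 100 with the largest smaller difference. A score was the mean log2 CPM (prior count 2) of its genes, compared by exact permutation of 6 against 6 libraries.

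Named genes followed a rule. Esr1 came first, in every group. For each comparison the rule then took the 6 largest rises and falls among called genes with at least 10 CPM in the higher group and complete separation of the libraries (except for differences of effects). It left out predicted, pseudogene, ribosomal, histone and immunoglobulin genes. Up to 4 called members per list with the largest change were added, genes were left out for length, and a few named by this rule are not reported. Comparisons, lists, this rule and the alternatives were fixed before the data were examined, except for 2 alternatives added later, which are named where used.

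The alternatives were the size factors of DESeq2 in edgeR, DESeq2 1.42.0 itself, no low count filter, 1 fit of all 51 libraries, each library left out in turn, the replicate number as a block, each mutant alone for N, an estimated correlation for the lists, and 50 or 200 signature genes. Other splits of the libraries were refitted, all 10 where 3 faced 3 and 40 drawn with a fixed seed elsewhere. The pipeline was tested on simulated counts with 200 changed genes and 3 libraries a side (6 for N). It recovered 39.1% of 2-fold and 65.2% of 4-fold changes in ML, 38.5% and 68.2% in Basal, 4.6% and 57.8% in LP, and 52.4% and 75.4% for N against ML. For the difference of effects in ML the values were 20.9% and 48.5%. False calls made up 2 to 9.1% of calls, and 0 true calls had the wrong sign.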

Results

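Bulk RNA of cells sorted from mouse mammary glands was sequenced in 51 libraries, 17 groups of 3. The glands carried either the wild-type estrogen receptor gene Esr1 (WT) or 1 of 2 substitutions in the ligand-binding domain of the receptor, D542G and Y541S. Animals were raised to 6 months of age, received pellets of estradiol and progesterone, and were then given vehicle or giredestrant by mouth for 4 days at 30 mg/kg daily. Giredestrant is an antagonist that binds the estrogen receptor and promotes its degradation. The sorted populations were mature luminal cells (ML), luminal progenitors (LP), basal cells (Basal) and a further population, called N here, which the labels list beside the other 3. ML and Basal cells were sequenced from every genotype with vehicle, which made 6 groups. With giredestrant, ML, LP and Basal cells of every genotype and N cells of both mutants made 11 groups. In each library 18949 to 22121 genes had a count. The 4 Y541S giredestrant groups had the highest mean counts (39.9 to 52.2 M), although Y541S giredestrant ML number 1 was the shallowest library (21.4 M), and WT vehicle ML libraries had a mean of 28.7 M. In WT vehicle ML libraries the 10 largest genes held 10.8% ± 0.525 (SD, n = 3) of all counts, the largest share of any group.

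Levels are CPM (mean ± SD), and ratios are log2 with standard error (SE). Every group had 3 libraries, and the joined N comparisons had 6 a side. The p-values measure the spread between these samples, since the labels do not state which libraries came from 1 animal. Complete separation of 3 libraries from 3 others happens in 10% of chance arrangements.

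Esr1, the gene that carries both substitutions, lies on chromosome 10 at 4611593 to 5005614 of GRCm38. In WT ML cells it stood at 290 ± 31 CPM with vehicle and at 218 ± 69 CPM with giredestrant, which was not a significant change (−0.43 ± 0.34, adjusted p = 0.345). With vehicle, D542G ML cells held 83.3 ± 14 CPM (−1.77 ± 0.35 against WT, adjusted p = 0.00273) and Y541S ML cells 84.7 ± 17 CPM (−1.74, adjusted p = 0.00635). Giredestrant left Esr1 in ML cells at 91.6 ± 51 CPM in D542G and 111 ± 27 CPM in Y541S. The differences from WT with giredestrant (−1.26 and −1.02) did not pass in edgeR (adjusted p = 0.0625 and 0.055). They passed in DESeq2 (adjusted p = 0.00683 and 0.0206) and in the fit of all 51 libraries (0.0274 and 0.0417), and that of D542G also without a low count filter (0.0465) or without D542G giredestrant number 1 (0.0208). In Basal cells with vehicle Esr1 was at 26 ± 6.9 CPM in WT, 23 ± 0.49 CPM in D542G and 17.3 ± 2.1 CPM in Y541S. Giredestrant raised it in D542G Basal cells to 63.8 ± 23 CPM (1.40, adjusted p = 0.0027) and in Y541S Basal cells to 36.6 ± 12 CPM (1.04, adjusted p = 0.018), beside 34 ± 6.5 CPM in WT. The Y541S call ended without Y541S vehicle number 2 (adjusted p = 0.0786) or 3 (0.0589), giredestrant number 2 (0.132), or giredestrant numbers 1 and 2 (0.218). LP cells held 94.1 ± 48 CPM in WT, 97 ± 17 CPM in D542G and 50.4 ± 19 CPM in Y541S. N cells had 268 ± 24 CPM in D542G and 293 ± 91 CPM in Y541S.

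**Figure D1:**
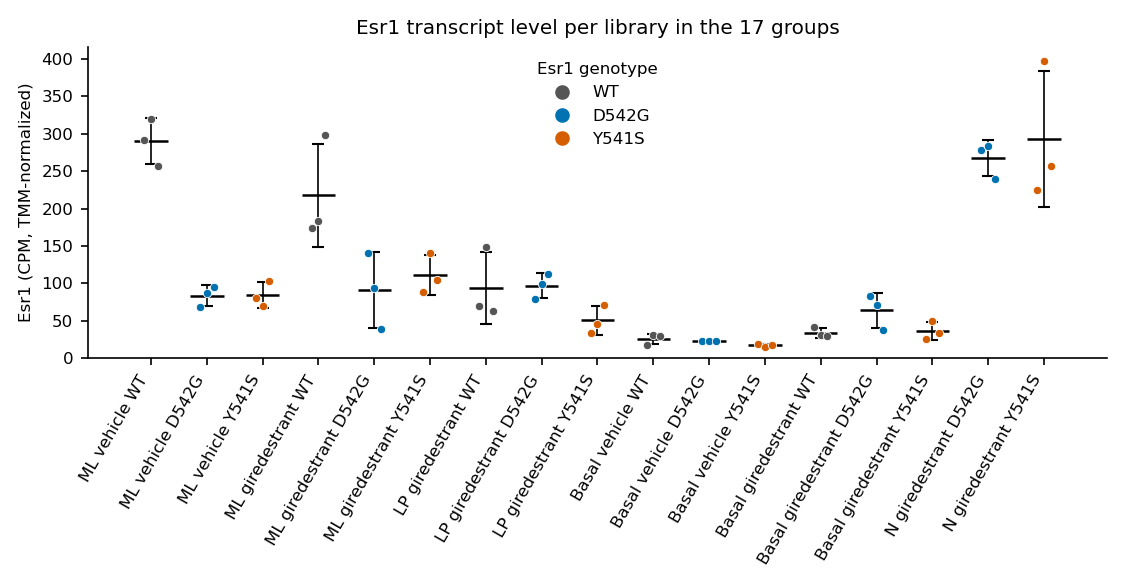
Esr1 level in each of the 17 groups, on the vertical axis in CPM after TMM scaling; points are libraries, lines are group means and bars are the SD of 3 libraries. WT vehicle ML cells (290 CPM) and N cells (268 and 293 CPM) had the highest means.

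The effect of the antagonist on ML cells, the WT population with the most Esr1, was tested in each genotype. In WT ML cells giredestrant lowered some estrogen receptor targets and raised others. Greb1, a receptor coactivator on chromosome 12 (16670615 to 16800886), fell from 172 ± 26 to 1.6 ± 0.71 CPM (−6.76 ± 0.64, adjusted p = 3.88e-06). Stc2, a secreted glycoprotein hormone on chromosome 11 (31357307 to 31370074), fell from 1300 ± 140 to 115 ± 80 CPM (−3.51 ± 0.43). Pgr, the progesterone receptor on chromosome 9 (8899833 to 8968611), fell from 296 ± 29 to 44.4 ± 30 CPM (−2.75 ± 0.37), and the transcription factor Myb fell by 2.72 (SE 0.26). The phosphatase Ptpn5 dropped from 512 ± 40 to 1.23 ± 1.6 CPM (−8.66), and the kallikrein Klk1 from 160 ± 170 to 0.148 ± 0.21 CPM. The serum amyloid gene Saa1 and the protease inhibitor Spink8, at 23.3 ± 9 and 15.2 ± 3.7 CPM with vehicle, had 0 counts with giredestrant. The largest rises were in Upk3a, a urothelial membrane protein (0.23 ± 0.15 to 388 ± 140 CPM), in the potassium channel Kcnk16 (9.57 ± 0.81), in the synaptic vesicle gene Sv2c (7.12), and in Fxyd2, a subunit of the sodium pump (4.54 ± 3.3 to 223 ± 89 CPM). Of 10 progesterone receptor targets 3 fell, 2 rose and 5 did not pass (camera adjusted p = 0.603). The glucocorticoid-inactivating enzyme Hsd11b2 (−4.37), the chaperone Fkbp5 (−2.05) and the kinase Sgk1 (−1.74) fell, and the calcitonin gene Calca rose from 89.5 ± 57 to 1590 ± 1300 CPM. In all, 5864 of 17181 genes changed in WT ML cells, 2939 higher and 2925 lower.

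Of 26 estrogen receptor target genes, 8 rose, 8 fell and 10 did not pass in WT ML cells (8 and 10 adjusted over the list alone). The list as a whole did not move (camera adjusted p = 0.162). Among the risers was Ccnd1, the G1 cyclin (1.03 ± 0.25). Cholesterol synthesis genes fell in 12 of 18 and rose in 0 (14 fell adjusted over the list alone), with camera adjusted p = 7.73e-06 and adjusted p = 0.698 with an estimated correlation. The sterol demethylase Cyp51 went from 206 ± 28 to 52.7 ± 13 CPM. Interferon response genes rose in 10 of 15 and fell in 1 (11 and 1 adjusted over the list alone), with camera adjusted p = 0.0136 and adjusted p = 0.959 with an estimated correlation. Ifi44 rose by 2.43 (SE 0.44) and the transcription factor Irf7 by 1.77. Squamous and keratinocyte genes fell in 5 of 13 and rose in 1, with a median of 0.06 against a mean of −0.68. Krt6a, a keratin of wounded epithelium, fell from 169 ± 31 to 3.57 ± 2.7 CPM. Of 13 luminal progenitor markers 6 rose and 1 fell, with a rise of 1.23 for the alveolar transcription factor Elf5, and of 11 epidermal growth factor receptor family and ligand genes 3 rose and 2 fell, Erbb4 by +2.10 and Erbb3 by −1.15. The Notch effector Heyl rose (1.68), the endothelial and platelet adhesion gene Vwf fell from 876 ± 99 to 150 ± 37 CPM, and Tgfb1 fell by 2.26. Of 32 proliferation genes 31 did not pass, and all 8 pericyte and all 4 skeletal muscle markers did not pass.

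In D542G ML cells giredestrant lowered 4 of the same receptor targets from lower starting levels. Greb1 fell from 54 ± 11 to 4.25 ± 1.5 CPM (−3.73 ± 0.56, adjusted p = 0.00102), Stc2 from 356 ± 72 to 46.6 ± 12 CPM (−2.99 ± 0.42) and Pgr from 100 ± 16 to 22.4 ± 2 CPM (−2.22 ± 0.37). Myb fell by 1.63. Other large falls were in the antimicrobial lectin Reg3b (−6.49), in Hsd11b2 (96.6 ± 68 to 2.27 ± 0.33 CPM) and in Ptpn5 (81.8 ± 18 to 1.98 ± 0.34 CPM). Large rises were in the desmosomal cadherin Dsc1 (0.0378 ± 0.065 to 10.6 ± 6.1 CPM), Fxyd2 (5.32 ± 0.67), Upk3a (5.04 ± 1.09) and the suprabasal keratins Krt1 (5.73) and Krt10 (5.26 ± 1.2 to 91.6 ± 76 CPM). Proliferation genes fell in 28 of 32 and rose in 0 (28 adjusted over the list alone), with camera adjusted p = 9.63e-16 and adjusted p = 0.516 with an estimated correlation. The survivin gene Birc5 fell from 73.9 ± 20 to 18 ± 3.2 CPM. Luminal progenitor markers rose in 5 of 13 and fell in 0 (9 adjusted over the list alone; camera adjusted p = 1.05e-04, adjusted p = 0.516 with an estimated correlation). The iron-binding milk protein Ltf rose from 156 ± 56 to 1600 ± 650 CPM and the complement regulator Cd55 by 1.47. The milk fat genes Btn1a1 (2.80) and Mfge8 (2700 ± 830 to 8550 ± 1500 CPM) rose among 4 risers of 15 milk and alveolar genes. The mucin Muc1 rose by 1.92 and Heyl by 1.69, while the collagen Col6a3 fell by 1.97. Of the 26 estrogen receptor targets 3 rose and 5 fell, with a median of 0.08 and a mean of −0.19. Immune cell markers rose in 5 of 13 and pericyte markers in 3 of 8. In all, 3546 genes changed, 1605 higher and 1941 lower, but 1176 did so without D542G vehicle number 2, 2297 without D542G vehicle number 3 and 1737 without D542G giredestrant number 2.

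In Y541S ML cells 6 of the 26 estrogen receptor targets rose, 5 fell and 15 did not pass (camera adjusted p = 0.955). Stc2 fell from 443 ± 120 to 66.2 ± 27 CPM (−2.82 ± 0.42, adjusted p = 5.30e-04), whereas Greb1 fell by 1.67 only, from 53 ± 1.6 to 17.8 ± 16 CPM (adjusted p = 0.0257). The Greb1 call ended without Y541S vehicle number 1 (adjusted p = 0.0548), vehicle number 3 (0.0676) or giredestrant number 2 (0.106). Greb1 stood at 35.4, 13.9 and 4.07 CPM in the giredestrant libraries numbered 1 to 3. The binding protein of insulin-like growth factors Igfbp4 rose by 1.63 and the matrix gene Tnxb fell from 75.1 ± 53 to 3 ± 2.7 CPM. Other large falls were in the transcription factor Irf4 (−4.96 ± 0.71) and the hormone receptor Mchr1 (14.1 ± 12 to 0.513 ± 0.031 CPM). The largest rises included Olah, which ends fatty acid synthesis in milk fat (4.56 ± 0.65, adjusted p = 4.06e-04), the hyaluronan synthase Has2 (0.62 ± 0.39 to 14.4 ± 11 CPM), the immunoglobulin transporter Pigr (1.49 ± 0.42 to 30.7 ± 31 CPM), Fxyd2 (4.42 ± 0.64) and Upk3a (4.57 ± 1.06). Of 15 milk and alveolar genes 11 rose and 0 fell (12 adjusted over the list alone), with camera adjusted p = 7.45e-05 and adjusted p = 0.408 with an estimated correlation. The beta-casein gene Csn2 was at 11400, 3470 and 27.8 CPM in the giredestrant libraries numbered 1 to 3, against 75.7 ± 110 CPM with vehicle (5.96, adjusted p = 0.0385). Its call ended without vehicle number 1 (0.114), vehicle number 3 (0.121), giredestrant number 1 (0.11) or giredestrant number 2 (0.067). With giredestrant number 3 alone the log2 ratio was −1.53.

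Markers of other cell types rose in the same Y541S ML libraries. Endothelial markers rose in 9 of 12 (camera adjusted p = 1.31e-05, adjusted p = 0.377 with an estimated correlation), with Kdr, a receptor of vascular endothelial growth factor, at 4.35 ± 0.94 and then 21.3 ± 6 CPM, and Pecam1 up by 2.17. Basal and myoepithelial markers rose in 9 of 20 (11 adjusted over the list alone; camera adjusted p = 5.66e-05, adjusted p = 0.522 with an estimated correlation), with Krt14 at 15.3 ± 2.2 and then 128 ± 69 CPM and the protein C receptor Procr up by 2.22. Pericyte markers rose in 6 of 8, fibroblast markers in 5 of 12 and epithelial to mesenchymal transition factors in 5 of 11, with 1 fall, in Tgfb1 (−1.40). The fibrillin gene Fbn1 rose by 3.24 and the fatty acid carrier Fabp4 by 2.20. Egfr rose from 27.1 ± 6.4 to 71.4 ± 14 CPM, Heyl by 2.01 and the interferon gene Ifit1 by 2.03. Proliferation genes passed in 3 of 32, among them the kinetochore gene Cenpf (1.71), and 0 of 10 progesterone receptor targets passed. In all, 4282 genes changed, 2054 higher and 2228 lower. The count was 2477 without Y541S vehicle number 3, 2395 without Y541S giredestrant number 2, and 1238 without giredestrant numbers 1 and 2, a setting chosen after the data were seen. Without those 2 libraries the calls of Igfbp4, Pigr, Krt14, Fbn1 and Fabp4 ended.

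Genes that rose in WT and in D542G ML cells numbered 802, where 274.6 were expected if the responses were independent, and 1044 fell in both, against 330.4 expected. For WT and Y541S the shared rises were 920 (351.4 expected) and the shared falls 1363 (379.3 expected). D542G and Y541S shared 696 rises (191.9 expected) and 948 falls (251.7 expected). Genes called in opposite directions were few, between 7 and 62 per pair of genotypes and direction.

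**Figure D2:**
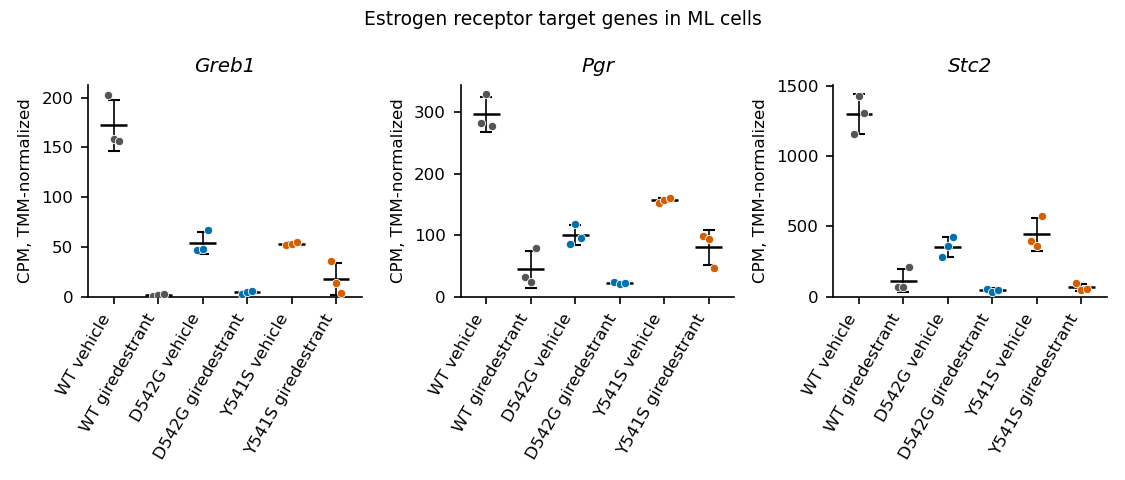
Levels of Greb1, Pgr and Stc2 in the 6 ML groups, on the vertical axis in CPM after TMM scaling; points are libraries, lines are group means and bars are the SD of 3 libraries. Greb1 went from 172 to 1.6 CPM with giredestrant in WT, from 54 to 4.25 CPM in D542G and from 53 to 17.8 CPM in Y541S.

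How the substitutions alone altered hormone-treated ML cells was read from the vehicle libraries. In D542G ML cells 7 of 26 estrogen receptor targets were lower than in WT, 4 were higher and 15 did not pass (camera adjusted p = 0.197). The growth factor amphiregulin (Areg) was at 294 ± 94 CPM against 1150 ± 330 CPM in WT (−1.94 ± 0.44, adjusted p = 0.00625), Stc2 at 356 ± 72 against 1300 ± 140 CPM (−1.84 ± 0.40) and Pgr at 100 ± 16 against 296 ± 29 CPM (−1.53 ± 0.35). The stem cell antigen Prom1 was lower by 2.52, the G protein subunit Gnb4 by 4.33 and the neuronal adhesion gene Lrrn2 by 5.93, although the Lrrn2 call ended in DESeq2. Higher genes included the proteoglycan Spock1 (119 ± 99 against 0.107 ± 0.12 CPM), the adrenaline-forming enzyme Pnmt (65.2 ± 56 against 0.165 ± 0.16 CPM), the cathepsin gene Ctsr (6.67), the neuropeptide Nmu (6.08) and Ccnd1 (277 ± 12 against 121 ± 9.7 CPM). Proliferation genes were higher in 29 of 32 and lower in 0 (31 adjusted over the list alone), with camera adjusted p = 8.77e-19 and adjusted p = 0.582 with an estimated correlation. The mitotic cyclin Ccnb2 was at 112 ± 20 against 24.2 ± 5.7 CPM and the kinase Cdk1 at 98.9 ± 42 against 24.6 ± 11 CPM. Mature luminal markers were lower in 7 of 13 and higher in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 7.04e-04, adjusted p = 0.582 with an estimated correlation). Interferon response genes were higher in 10 of 15 (11 higher and 2 lower adjusted over the list alone; camera adjusted p = 2.11e-04, adjusted p = 0.693 with an estimated correlation), with Gbp3 up by 2.11 and Oas1a by 2.21. Cholesterol synthesis genes were lower in 8 of 18 (camera adjusted p = 0.00236, adjusted p = 0.693 with an estimated correlation). Among basal and myoepithelial markers 4 of 20 were higher, with Krt14 at 104 ± 98 against 10.6 ± 4.3 CPM and the Notch ligand Jag2 up by 2.08. Cldn4, a tight junction gene, was lower by 1.34, Erbb3 by 1.04 and Vwf by 1.98. Fibroblast, pericyte, immune cell, adipocyte and skeletal muscle markers passed in 0 genes each. In all, 3370 genes differed, 1610 higher and 1760 lower, with 1907 without WT vehicle number 2, 2212 without D542G vehicle number 1 and 2208 without D542G vehicle number 2.

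Y541S ML cells with vehicle differed from WT in 1867 genes, 823 higher and 1044 lower. The lymphocyte antigen gene Ly6d was at 54 ± 38 against 1090 ± 500 CPM in WT (−4.30 ± 0.61, adjusted p = 0.00116), the cytochrome Cyp2s1 at 4.14 ± 4.1 against 63.3 ± 8.6 CPM and the citrullinating enzyme Padi2 at 12 ± 14 against 173 ± 49 CPM. The secreted regulator of chloride channels Clca1 was at 47.8 ± 75 against 0.0131 ± 0.023 CPM, and Spock1 was higher by 8.67. Gnb4 (−3.37) and Prom1 (−1.68) were lower, as in D542G. The receptor target Myb was lower by 1.09 (adjusted p = 0.0121), a call that ended in the fit of all 51 libraries. Of 26 estrogen receptor targets 5 were lower, 2 higher and 19 did not pass. Cholesterol synthesis genes were lower in 7 of 18 and higher in 0 (9 lower adjusted over the list alone), with camera adjusted p = 1.29e-07 and adjusted p = 0.504 with an estimated correlation. The sterol oxidase Msmo1 was lower by 1.38. Proliferation genes were higher in 9 of 32 (21 adjusted over the list alone; camera adjusted p = 3.66e-11, adjusted p = 0.504 with an estimated correlation). Ccnb2 was at 76.6 ± 8.4 against 24.2 ± 5.7 CPM, a call that ended without WT vehicle number 2 (adjusted p = 0.0742) and in the fit of all 51 libraries (0.0642). Endothelial markers were lower in 3 of 12 (9 adjusted over the list alone; camera adjusted p = 4.92e-05, adjusted p = 0.504 with an estimated correlation). Immediate early and heat shock genes passed in 0 of 14 and epidermal growth factor receptor family genes in 0 of 11. The total fell to 1021, 686 and 1038 genes without WT vehicle numbers 1, 2 and 3, and to 835 and 648 without Y541S vehicle numbers 1 and 2.

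The mutants were also compared with WT between the giredestrant libraries. D542G ML cells then differed from WT in 447 genes, 318 higher and 129 lower. Krt6a (chromosome 15, 101689910 to 101694307) was at 115 ± 67 CPM against 3.57 ± 2.7 CPM in WT (5.03 ± 0.77, adjusted p = 0.00545). The alarmin cytokine Il33 was at 142 ± 100 against 6.12 ± 3.6 CPM (4.53 ± 0.69, adjusted p = 0.00545), the retinoic acid binding protein Crabp1 at 15.2 ± 8.9 against 1.06 ± 0.45 CPM (3.82 ± 0.52) and Col6a3 was higher by 2.65. Krt6a (1840 ± 700 CPM), Il33 (2190 ± 1300 CPM) and Crabp1 (150 ± 46 CPM) were higher still in N cells of both mutants. WT had no N library, and whether such cells in the mutants' other gates contributed to these differences was not tested. The Wnt receptor Ror2 was lower by 2.25 (6.06 ± 1.9 against 28.9 ± 6.1 CPM), and the calcium channel Trpc6 by 2.56, a call that ended without D542G giredestrant number 3 (adjusted p = 0.0533). Squamous and keratinocyte genes were higher in 7 of 13 and lower in 0 (9 adjusted over the list alone), with camera adjusted p = 1.66e-10 and adjusted p = 0.063 with an estimated correlation. Cholesterol synthesis genes were higher in 4 of 18. Basal and myoepithelial markers were higher in 4 of 20 (12 adjusted over the list alone), with camera adjusted p = 4.75e-09 and adjusted p = 0.211 with an estimated correlation. Immune cell markers were higher in 4 of 13 (12 adjusted over the list alone), with camera adjusted p = 7.05e-09 and adjusted p = 0.211 with an estimated correlation. Of 32 proliferation genes 1 passed, 13 of 13 mature luminal markers and 10 of 10 progesterone receptor targets did not pass. The whole count was 110 without WT giredestrant number 1, 103 without WT giredestrant number 3, 132 without D542G giredestrant number 3, and 1314 in DESeq2.

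Y541S ML cells with giredestrant differed from WT in 2599 genes, 1439 higher and 1160 lower. Greb1 was higher by 3.42 (SE 0.57, adjusted p = 0.00274), at 17.8 ± 16 against 1.6 ± 0.71 CPM. The casein genes led the rises, with Csn2 (chromosome 5, 87692624 to 87699630) at 4980 ± 5900 against 2.14 ± 2.5 CPM and Csn1s1 at 1210 ± 1100 against 5.16 ± 5.6 CPM. Also higher were the opioid precursor Penk (271 ± 270 against 0.913 ± 1.1 CPM) and the homeobox gene Rhox5 (106 ± 89 against 0.297 ± 0.25 CPM). Lower genes included the synaptic gene Nrxn3 (−6.25 ± 0.99), the neuregulin Nrg4 (1.56 ± 0.98 against 19.2 ± 5.1 CPM), the peptide hormone Enho (−3.62) and the matrix gene Ccbe1 (−3.40). Proliferation genes were higher in 16 of 32 and lower in 0 (21 adjusted over the list alone), with camera adjusted p = 4.05e-13 and adjusted p = 0.39 with an estimated correlation. Mki67, the Ki-67 antigen gene, was at 14.2 ± 2.3 against 2.07 ± 1.1 CPM and Cenpf was higher by 2.43. Milk and alveolar genes were higher in 9 of 15 (11 higher and 1 lower adjusted over the list alone; camera adjusted p = 2.67e-05, adjusted p = 0.39 with an estimated correlation). Fibroblast markers were higher in 6 of 12, with Col6a3 at 32.3 ± 20 against 2.19 ± 0.47 CPM, and squamous genes in 4 of 13, with Krt6a up by 4.85 and the calprotectin subunit S100a8 by 3.91. Of 14 immediate early and heat shock genes 5 were lower, among them Fosb (501 ± 82 against 1430 ± 130 CPM), and 1 was higher. Mature luminal markers were lower in 4 of 13 and higher in 0. The count was 1493 and 1236 without WT giredestrant numbers 1 and 2, and 912 and 1593 without Y541S giredestrant numbers 1 and 2. Without both of the last, 125 genes passed, and of the genes named here Mki67, Cenpf, S100a8 and Col6a3 kept their calls while the others lost them.

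Interactions tested whether the giredestrant response itself differed from that of WT. For D542G ML cells it differed in 1129 genes, 718 upward and 411 downward from the WT effect. Kcnk16 rose less than in WT (difference −7.61 ± 0.99, adjusted p = 0.00116), as did Sv2c (−5.76). Krt6a fell in WT and had no significant change in D542G (0.05, adjusted p = 0.964), a difference of 5.67 ± 0.98 (adjusted p = 0.0042). The zinc transporter Slc39a2 (5.59), the lipid-binding gene Bpifc (5.14) and Gnb4 (4.97) likewise fell less than in WT. Cholesterol synthesis genes differed upward in 7 of 18 and downward in 0 (10 adjusted over the list alone; camera adjusted p = 4.31e-08, adjusted p = 0.304 with an estimated correlation). Cyp51, for example, differed by 1.70. Interferon response genes differed downward in 6 of 15 (9 adjusted over the list alone; camera adjusted p = 4.57e-06, adjusted p = 0.413 with an estimated correlation), led by Oas1a (−3.48) and Ifi44 (−3.11). Proliferation genes differed downward in 3 of 32 (19 adjusted over the list alone; camera adjusted p = 2.37e-09, adjusted p = 0.475 with an estimated correlation), with Ccnb2 at −2.95. Squamous genes differed upward in 4 of 13. Of 40 rearrangements of the libraries, 1, the real one, gave this many genes and the next gave 758. The count was 663 and 551 without WT vehicle numbers 1 and 2, 463 without D542G vehicle number 2, 572 without WT giredestrant number 1, 724 without D542G giredestrant number 1, and 2111 in DESeq2.

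For Y541S ML cells the response differed from that of WT in 994 genes, 684 upward and 310 downward. Greb1 differed by 5.09 (SE 0.76, adjusted p = 0.00218), Ptpn5 by 5.06 and the receptor tyrosine kinase Ret by 3.13. The effects on Kcnk16 (−8.18 ± 0.97), Nrxn3 (−8.63 ± 1.28) and Nrg4 (−4.25) differed downward from those in WT. Of 26 estrogen receptor targets 7 differed upward and 1 downward (9 and 1 adjusted over the list alone; camera adjusted p = 0.00427, adjusted p = 0.161 with an estimated correlation). Cholesterol synthesis genes differed upward in 7 of 18 (10 adjusted over the list alone; camera adjusted p = 6.56e-09, adjusted p = 0.161 with an estimated correlation), with Cyp51 at 1.66. Endothelial markers differed upward in 6 of 12 (camera adjusted p = 6.56e-09, adjusted p = 0.161 with an estimated correlation), with Kdr at 2.66 and Pecam1 at 2.50. S100a8 differed by 5.34 and Krt6a by 4.99, in a squamous list with a median of −0.02 and a mean of 1.10. Of 40 rearrangements of the libraries 2 gave at least this many genes, and the other one gave 1000. Each of 8 libraries moved the count when left out, namely WT vehicle 1 and 2 (518 and 568), Y541S vehicle 1 and 2 (563 and 616), WT giredestrant 1 and 2 (555 and 625) and Y541S giredestrant 1 and 2 (519 and 628). DESeq2 gave 1891 genes. Without both of those Y541S giredestrant libraries 167 genes passed, Greb1, Kcnk16 and S100a8 among them, and the calls of the other genes named here ended.

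Basal cells, which held far less Esr1, were tested for the same effect of the antagonist. In WT Basal cells Gpx3, a secreted glutathione peroxidase, fell from 2400 ± 1500 to 64.4 ± 27 CPM (−5.25 ± 0.67, adjusted p = 0.0014). Greb1 fell from 16.4 ± 3 to 3 ± 0.63 CPM (−2.49 ± 0.36), Ccnd1 from 72.1 ± 16 to 27 ± 14 CPM (−1.46), the haptoglobin gene Hp (−4.58), the chemokine Cxcl15 (−4.06) and the myosin gene Myh11 (−1.57), a call that ended in the fit of all 51 libraries. Upk3a rose from 0.108 ± 0.12 to 36.8 ± 25 CPM. Proliferation genes fell in 12 of 32 (17 adjusted over the list alone), with camera adjusted p = 2.85e-18 and adjusted p = 0.974 with an estimated correlation, and the cell-cycle transcription factor E2f1 fell by 2.49. Cholesterol synthesis genes fell in 6 of 18 (camera adjusted p = 7.40e-05, adjusted p = 0.974 with an estimated correlation). Of 26 estrogen receptor targets 2 rose and 4 fell. In 12 lists, among them fibroblast, endothelial and interferon response genes, 0 genes passed. The total was 1901 genes, 779 higher and 1122 lower, with 621 and 766 without WT vehicle numbers 1 and 3, 493 and 588 without WT giredestrant numbers 1 and 2, and 2874 in DESeq2.

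D542G Basal cells had the largest Basal response, with 2162 genes higher and 2687 lower, 4849 in all. Proliferation genes fell in 31 of 32 (camera adjusted p = 8.61e-14, adjusted p = 0.398 with an estimated correlation). The mitotic kinase Plk1 fell from 54.6 ± 28 to 4.43 ± 2.5 CPM (−3.71 ± 0.88, adjusted p = 0.0069), the cyclin Ccna2 from 136 ± 38 to 16.1 ± 6.9 CPM and the ribonucleotide reductase subunit Rrm2 from 121 ± 50 to 15.5 ± 4.5 CPM. Il33 rose from 23.3 ± 9 to 320 ± 200 CPM (3.71 ± 0.59), the granulocyte growth factor Csf3 by 3.57, and Areg from 19 ± 2.8 to 210 ± 100 CPM (3.39 ± 0.71, adjusted p = 0.00371). Areg was among 6 of 26 estrogen receptor targets that rose, and 4 fell. The related ligand Hbegf rose by 1.73. Igfbp4 and the small G protein gene Rab31 fell by 1.32 and 1.51, and the Wnt inhibitor Wif1 by 1.42, a call that ended in the fit of all 51 libraries. Luminal genes rose, with 8 of 11 pan-luminal and epithelial adhesion genes higher (10 adjusted over the list alone; camera adjusted p = 1.17e-05, adjusted p = 0.398 with an estimated correlation). Krt18 went from 182 ± 83 to 846 ± 290 CPM, Muc1 rose by 2.37 and Ltf by 3.54. Krt17 rose from 3110 ± 1400 to 8670 ± 3000 CPM and Krt16 from 8.66 ± 4.1 to 56.6 ± 16 CPM. Endothelial markers rose in 9 of 12 (12 adjusted over the list alone; camera adjusted p = 1.17e-05, adjusted p = 0.398 with an estimated correlation), with Flt1 up by 1.81, and the pericyte gene Rgs5 rose by 1.85. Interferon response genes fell in 6 of 15 (10 adjusted over the list alone), with Oas1a down by 2.51. The count was 2135 without D542G vehicle number 2, and 3191 and 3015 without D542G giredestrant numbers 1 and 2.

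In Y541S Basal cells 2594 genes changed, 1399 higher and 1195 lower. Aqp3, a water and glycerol channel, rose from 2.35 ± 0.78 to 39.2 ± 15 CPM (4.03 ± 0.38, adjusted p = 8.44e-05), Il33 from 2.63 ± 0.18 to 40.6 ± 26 CPM and Krt16 from 3.65 ± 0.6 to 28.5 ± 2.6 CPM. The transcription factor Sox9 rose from 351 ± 12 to 782 ± 45 CPM (1.12 ± 0.14), Myh11 from 538 ± 150 to 2120 ± 17 CPM, Notch1 by 1.33 and the coregulator Nrip1 by 1.05. The repressor Id4 fell in all 3 genotypes, here by 1.18, although these calls, and that of Fos, ended in the fit of all 51 libraries. Fos fell by 1.05 among 4 falls of 14 immediate early and heat shock genes, the chromatin gene Samd1 by 2.38 and the claudin Cldn10 by 2.23. Milk and alveolar genes rose in 8 of 13 (11 adjusted over the list alone; camera adjusted p = 3.25e-05, adjusted p = 0.274 with an estimated correlation), with Csn2 at 772 ± 690 against 9.89 ± 11 CPM. Pan-luminal genes rose in 6 of 11, endothelial markers in 9 of 12 and Notch pathway genes in 5 of 13, and 0 of 32 proliferation genes passed. The count was 1610 and 1186 without Y541S vehicle numbers 2 and 3, 1037 without Y541S giredestrant number 2, and 121 without giredestrant numbers 1 and 2. Without that pair Aqp3, Il33, Krt16, Sox9, Id4 and Samd1 kept their calls and Myh11, Notch1, Nrip1, Fos, Cldn10 and Csn2 did not. WT and D542G Basal cells shared 324 rises (98.1 expected) and 665 falls (175.6 expected), and D542G and Y541S shared 613 and 622 (176.1 and 187 expected). WT and Y541S shared 158 and 255 (63.5 and 78.1 expected), with 27 and 66 genes called in opposite directions.

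Mutant and WT Basal cells differed little with vehicle. In D542G 9 genes were higher and 1 lower, led by Il33 (23.3 ± 9 against 1.47 ± 0.4 CPM, 3.97 ± 0.65, adjusted p = 0.0408), the hyaluronan-associated gene Itih2 (3.69) and the proteoglycan Cspg4 (45.3 ± 13 against 9.1 ± 2.9 CPM). In Y541S 19 genes were higher and 8 lower. They included Cspg4 (2.17), the neuronal regeneration gene Nrep (306 ± 43 against 80.8 ± 19 CPM) and Hbegf (−1.53). Each call named in these 2 comparisons ended with at least 1 library left out. Without 1 library the D542G count was 18, 0 and 2 (WT vehicle 1, 2 and 3) or 0, 0 and 6 (D542G vehicle 1, 2 and 3). The Y541S count was 0 and 1 without WT vehicle 2 and 3, and 0, 0 and 100 without Y541S vehicle 1, 2 and 3. DESeq2 called 241 genes for D542G and 679 for Y541S. At unadjusted p below 0.05, 1650 and 2529 genes stood out.

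With giredestrant, D542G Basal cells differed from WT in 853 genes, 434 higher and 419 lower. Il33 was at 320 ± 200 against 2.59 ± 1.1 CPM (6.90 ± 0.70, adjusted p = 2.82e-04), Krt6a at 157 ± 68 against 1.66 ± 0.18 CPM (6.52 ± 0.77) and Crabp1 at 43.7 ± 24 against 1.12 ± 1.2 CPM. The aldehyde dehydrogenase Aldh3a1 was higher by 5.22, the inhibitor of inflammatory signalling Tnip3 by 4.86 and Myb by 2.84. Pan-luminal genes were higher in 7 of 11 (10 adjusted over the list alone; camera adjusted p = 4.31e-13, adjusted p = 0.133 with an estimated correlation), with Cldn4 at 163 ± 77 against 24 ± 4.1 CPM. Squamous genes were higher in 4 of 12 (6 adjusted over the list alone; camera adjusted p = 1.60e-06, adjusted p = 0.0873 with an estimated correlation). The count was 166 and 372 without WT giredestrant numbers 1 and 3, 345 and 394 without D542G giredestrant numbers 1 and 2, and 1766 in DESeq2.

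Y541S Basal cells with giredestrant differed from WT in 2397 genes, 1304 higher and 1093 lower. Greb1 was at 21 ± 12 against 3 ± 0.63 CPM (2.77 ± 0.36, adjusted p = 4.41e-04), Myh11 at 2120 ± 17 against 297 ± 21 CPM (2.80 ± 0.33), Cspg4 at 85.2 ± 29 against 15.8 ± 3.7 CPM (2.39 ± 0.32) and Krt6a was higher by 5.39. Csn2 was at 772 ± 690 against 0.756 ± 0.44 CPM, Ccnd1 at 79.8 ± 3.2 against 27 ± 14 CPM and the cholesterol enzyme Sqle higher by 1.03. The stress-response gene Ankrd1 (−4.93), the ligand Wnt9a (−3.04) and the granule protease Prtn3 (−2.80) were lower. Milk and alveolar genes were higher in 7 of 13 (camera adjusted p = 1.44e-05, adjusted p = 0.159 with an estimated correlation), and Wnt pathway targets were higher in 4 of 13 and lower in 1. Basal and myoepithelial markers were higher in 3 of 20 and lower in 3, with a median of −0.01 and a mean of 0.10. The count was 1248 and 1436 without WT giredestrant numbers 1 and 2, 1276 and 1189 without Y541S giredestrant numbers 1 and 2, and 121 without the last pair. Greb1, Myh11, Cspg4 and Krt6a kept their calls without that pair, and the other genes named lost theirs.

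The giredestrant response of D542G Basal cells differed from that of WT in 108 genes, 41 upward and 67 downward, a split that turned in the fit of all 51 libraries (86 and 61). Gpx3 differed by 4.88 (SE 0.83, adjusted p = 0.0251), since it stayed at 1780 ± 790 CPM in D542G, the selectin Sele by 3.43 and Csf3 by 3.95, and the lysosomal gene Lamp5 by −8.02. Each of these calls ended with at least 1 library left out, that of Sele also in the fit of all 51 libraries, and 2 of 40 rearrangements of the libraries gave as many genes, the other one 262. Left out in turn, WT vehicle 1 to 3 gave 276, 8 and 7 genes, D542G vehicle 1 to 3 gave 175, 12 and 3, WT giredestrant 1 to 3 gave 3, 609 and 25, and D542G giredestrant 1 to 3 gave 49, 11 and 273, with 898 in DESeq2. In Y541S Basal cells the response differed in 766 genes, 473 upward and 293 downward. Myh11 differed by 3.50 (SE 0.45, adjusted p = 0.00101), Sele by 3.88, Krt6a by 4.71, Gpx3 by 4.66 and Ccnd1 by 2.06, and Prtn3 by −3.18. Proliferation genes differed upward in 3 of 32 (12 adjusted over the list alone; camera adjusted p = 7.30e-14, adjusted p = 0.319 with an estimated correlation). The real arrangement alone of 40 gave this many genes, and the next gave 71. The count was 485 and 457 without WT vehicle 1 and 3, 362 and 418 without Y541S vehicle 2 and 3, 278 without WT giredestrant 1, 426 and 323 without Y541S giredestrant 1 and 2, and 1602 in DESeq2. Without that Y541S pair 67 genes passed, Myh11 and Sele among them, and Krt6a, Gpx3, Ccnd1 and Prtn3 did not.

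**Figure D3:**
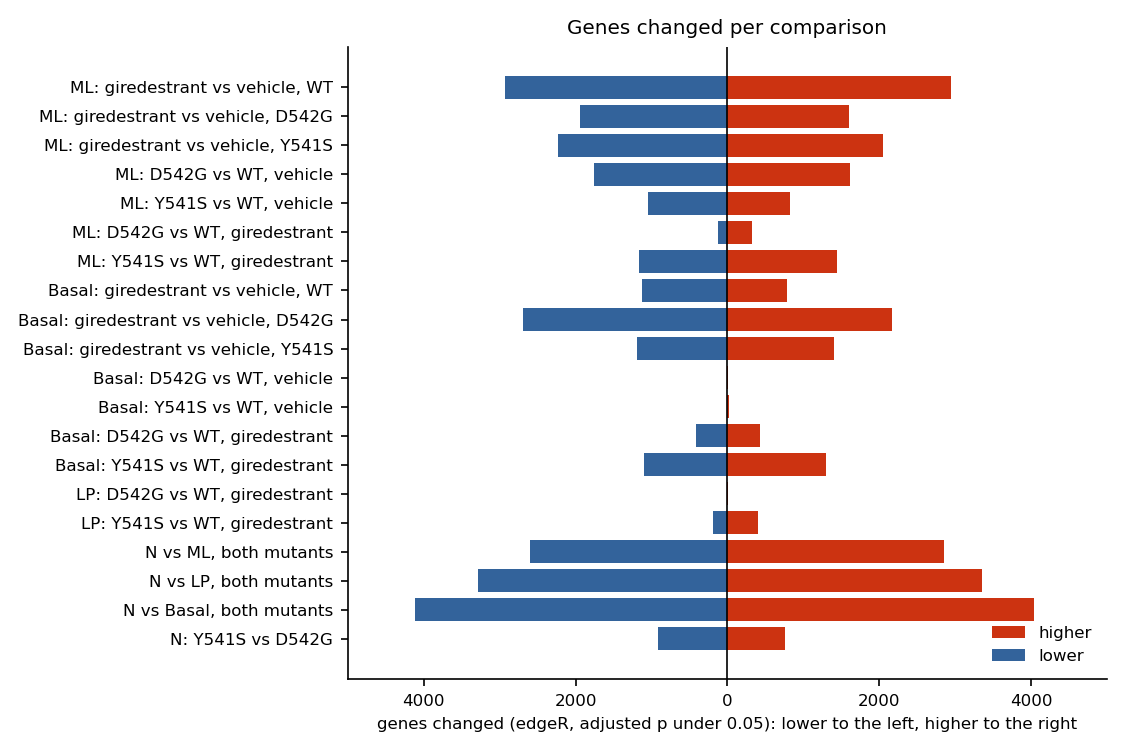
Number of genes at adjusted p below 0.05 in 20 comparisons, on the horizontal axis, with bars for genes lower in the first group drawn to the left and bars for genes higher drawn to the right. The largest counts within a cell type were for giredestrant in WT ML cells (5864) and D542G Basal cells (4849), and the smallest for mutant against WT in D542G LP cells (5) and in Basal cells with vehicle (10 and 27).

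LP cells were compared between genotypes with giredestrant only. In D542G 5 of 16569 genes were higher and 0 lower, among them the granule proteoglycan Srgn (33.1 ± 4.9 against 4.35 ± 0.99 CPM, 2.91 ± 0.25, adjusted p = 0.00685), Krt6a (4.38) and the microtubule-associated gene Map7d1 (76.1 ± 14 against 21.4 ± 5 CPM). In Y541S 402 genes were higher and 185 lower. Csn2 was at 5770 ± 5200 against 10.8 ± 3.4 CPM (9.0 ± 1.59, adjusted p = 0.027), Cenpf at 31.2 ± 1.4 against 4.4 ± 1.9 CPM (2.76 ± 0.35) and the transcriptional corepressor Irf2bp2 at 117 ± 6.5 against 475 ± 35 CPM (−2.08 ± 0.32). Fibroblast markers were higher in 11 of 12 (12 adjusted over the list alone; camera adjusted p = 1.44e-21, adjusted p = 0.354 with an estimated correlation), with Col3a1 at 3230 ± 2000 against 136 ± 54 CPM. Basal and myoepithelial markers were higher in 2 of 20 (13 adjusted over the list alone; camera adjusted p = 7.85e-08, adjusted p = 0.354 with an estimated correlation). Every named LP call ended with at least 1 library left out. The D542G count was 0, 42 and 0 without WT giredestrant 1, 2 and 3, and 0 and 1 without D542G giredestrant 1 and 2. For Y541S it was 0, 110 and 0 without WT giredestrant 1, 2 and 3, 52, 7 and 979 without Y541S giredestrant 1, 2 and 3, and 0 without the first pair of these. DESeq2 called 735 and 1900 genes, and the fit of all 51 libraries 1310 (560 higher and 750 lower) and 2657.

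N cells of the mutants with giredestrant were compared with each other population of the same animals' groups, D542G and Y541S joined. Against ML cells, N cells had far more of the basal keratin Krt14 (chromosome 11, 100203162 to 100207548) at 5970 ± 4400 against 224 ± 140 CPM (4.52 ± 0.46, adjusted p = 5.80e-07). The basal transcription factors Trp63 (531 ± 200 against 31.1 ± 20 CPM) and Snai2 (4.47) were higher, as were the ligands Wnt10a (170 ± 100 against 6.34 ± 4.5 CPM) and Jag2 (4.27) and the wound keratins Krt6a (1840 ± 700 against 109 ± 50 CPM) and Krt16 (4.46). Esr1 was also higher, at 280 ± 61 against 101 ± 38 CPM (1.5 ± 0.27, adjusted p = 2.88e-04). Receptor targets were higher too, with Igfbp4 at 465 ± 140 against 44.4 ± 14 CPM, Stc2 higher by 2.64 and Myb by 2.41. Whether this goes back to Esr1 was not tested. Igfbp4 was also above ML in Basal cells (176 ± 76 CPM), while Stc2 (38.4 ± 18 CPM) and Myb (10.5 ± 7.1 CPM) were not. Of 26 estrogen receptor targets 16 were higher and 2 lower in N than in ML (17 and 4 adjusted over the list alone). The camera adjusted p was 4.27e-06, and 0.0259 with an estimated correlation. Luminal progenitor markers were lower in 11 of 13 and higher in 1 (camera adjusted p = 1.31e-12, adjusted p = 0.00408 with an estimated correlation). Kit was at 82.4 ± 28 against 630 ± 180 CPM, Wfdc18 lower by 3.01 and Ltf by 2.94. Also lower were the receptor kinase Erbb4 (−3.32), the mucins Muc4 (−3.64) and Muc1 (−2.69), Ccnd1 (−2.17), Heyl (−2.26) and Krt8 (383 ± 150 against 965 ± 200 CPM). Basal and myoepithelial markers were higher in 11 of 20 (camera adjusted p = 4.22e-10, adjusted p = 0.238 with an estimated correlation), pan-luminal genes lower in 7 of 11, and interferon response genes lower in 8 of 15, with Ifit2 down by 1.77. In all, 5456 of 18247 genes differed, 2858 higher and 2598 lower, with 2153 in Y541S alone and 1971 when number 3 was the only Y541S library. Each gene named here and in the next 2 paragraphs kept its call in that fit.

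Against LP cells 6644 genes differed, 3357 higher and 3287 lower, with 4023 in Y541S alone and 2641 with number 3 as the only Y541S library. Krt6a was higher by 6.71 (SE 0.54, adjusted p = 2.28e-08), the serotonin transporter Slc6a4 by 7.21 and the surfactant gene Sftpc by 7.32. Esr1 was higher by 2.03, Pgr by 1.64 and Areg at 1000 ± 240 against 231 ± 140 CPM. Of 26 estrogen receptor targets 17 were higher and 5 lower (camera adjusted p = 4.16e-06, adjusted p = 0.0365 with an estimated correlation). Squamous genes were higher in 11 of 15 and lower in 1 (camera adjusted p = 3.66e-08, adjusted p = 0.0381 with an estimated correlation), with the desmoglein Dsg3 up by 6.12. Luminal progenitor markers were lower in 12 of 13 and higher in 1 (camera adjusted p = 5.99e-13, adjusted p = 0.00276 with an estimated correlation). The neutrophil lipocalin Lcn2 was at 130 ± 29 against 1170 ± 340 CPM and Elf5 at 22.7 ± 9.2 against 182 ± 32 CPM. Fibroblast markers were lower in 12 of 12 (adjusted p = 0.218 with an estimated correlation), with the collagen Col1a2 at 31.9 ± 30 against 848 ± 950 CPM.

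Against Basal cells 8148 genes differed, 4040 higher and 4108 lower, with 4578 in D542G alone and 4693 with number 3 as the only Y541S library. The contractile genes named here were far lower in N cells. Acta2, smooth muscle actin, was at 214 ± 23 against 12300 ± 2900 CPM (−5.83 ± 0.60, adjusted p = 1.90e-07), Myh11 at 23.3 ± 4 against 1550 ± 730 CPM, the calponin Cnn1 at 32.4 ± 4.8 against 1970 ± 440 CPM and the actin gene Actg2 lower by 7.15. The intermediate filament Vim was lower by 2.81 and the stem cell receptor Lgr5 (−3.18). Luminal genes were higher, with Cldn4 at 1300 ± 270 against 136 ± 64 CPM, the pioneer factor Foxa1 up by 3.24, the prolactin receptor Prlr by 2.38, Krt7 by 2.37 and Krt19 at 4010 ± 2200 against 1010 ± 460 CPM. Basal and myoepithelial markers were lower in 14 of 20 and higher in 0 (15 adjusted over the list alone; camera adjusted p = 3.45e-10, adjusted p = 0.186 with an estimated correlation). Pan-luminal genes were higher in 10 of 11 (camera adjusted p = 8.46e-09, adjusted p = 0.154 with an estimated correlation), mature luminal markers higher in 10 of 13 and lower in 1 (camera adjusted p = 9.27e-05, adjusted p = 0.186 with an estimated correlation), and squamous genes higher in 12 of 15.

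**Figure D4:**
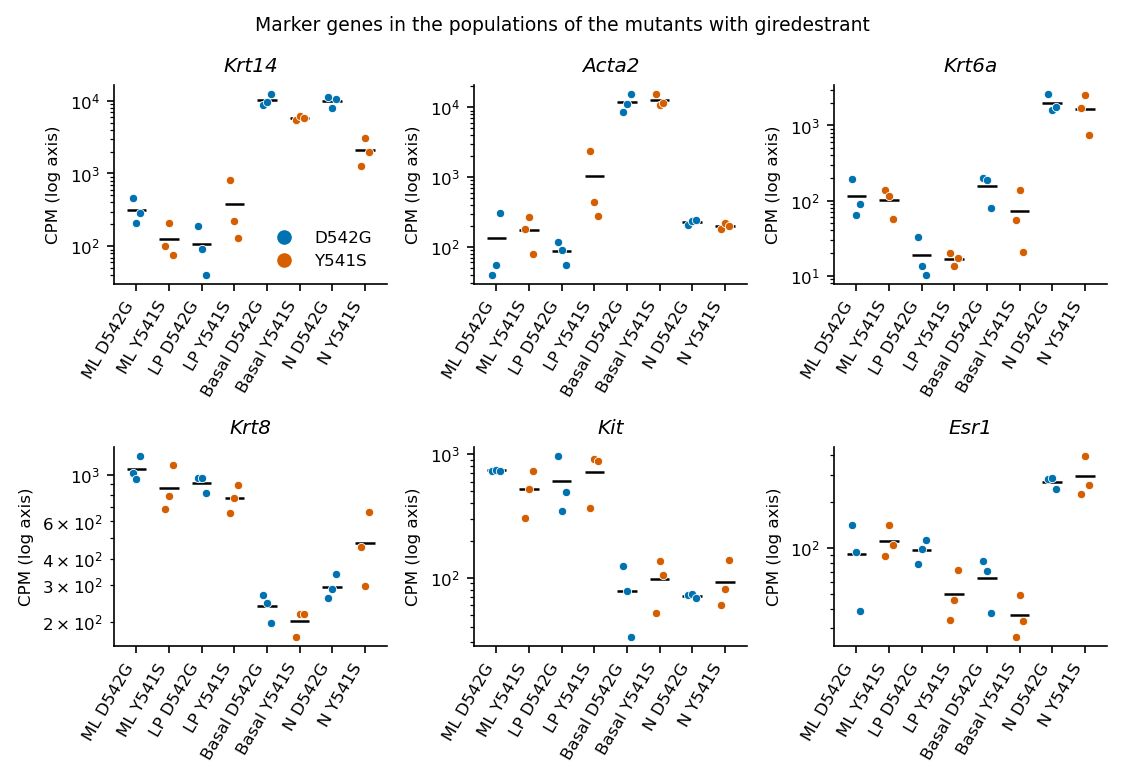
Krt14, Acta2, Krt6a, Krt8, Kit and Esr1 in ML, LP, Basal and N cells of the mutants with giredestrant, on a log vertical axis in CPM after TMM scaling; points are libraries and lines are group means. Over 6 libraries N had Krt14 at 5970, Acta2 at 214 and Krt6a at 1840 CPM.

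A total of 1128 genes were higher in N than in each of the other 3 populations and 940 were lower. Of these, 341 and 198 had all N libraries outside the range of every other library, and 892 genes lay between ML and Basal cells. The epithelial mitogen Epgn was at 378 ± 260 CPM in N against 22.9 ± 12, 6.4 ± 4.5 and 20.7 ± 12 CPM in ML, LP and Basal cells, and Aldh3a1 at 285 ± 210 against 12.7 ± 13, 4.47 ± 2.6 and 10 ± 8.1 CPM. The transcription factor Sox10 was lowest in N, at 23.3 ± 9.3 CPM against 159 ± 50, 180 ± 41 and 149 ± 29 CPM, and Ntng1, a guidance cue for axons, at 7.61 ± 2.3 against 78 ± 44, 107 ± 59 and 107 ± 14 CPM. Taken alone, D542G called 562 higher and 466 lower and Y541S 490 and 414, of which 269 and 200 were called in both. The counts were 314 and 329 with number 3 as the only Y541S library.

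Scores from genes that marked 1 population against both others in the 9 WT giredestrant libraries were read in the 24 mutant ones. The Basal score, a mean of 100 log2 levels, was 1.73 ± 0.46 in N, −0.02 ± 0.5 in ML, 0.67 ± 1.34 in LP and 5.27 ± 0.27 in Basal cells. N differed from ML by 1.75 and from Basal by −3.54, each with an exact 2-sided permutation p of 0.00216, the smallest that 924 splits allow. Only 1 gene, Rin3, marked ML cells, and N and ML did not differ in it (0.12, exact p = 0.556). Likewise 1 gene, Mmp3, marked LP cells, and N differed from LP in it by −4.62 (exact p = 0.00216, adjusted p = 0.00648). Its level in LP libraries went with a fibroblast gene, at 5.31 to 8.04 in the 4 with Col1a1 at 597 to 2860 CPM, against 3.09 and 4.17 in the 2 with Col1a1 at 80.7 and 70.4 CPM, so this score does not measure LP cells alone. A score from 100 genes shared by ML and LP cells, chosen after the data were seen, was 0.80 ± 0.23 in N, 2.09 ± 0.27 in ML, 1.95 ± 0.35 in LP and −0.40 ± 0.48 in Basal cells, so N lay 1.29 below ML on it (exact p = 0.00216).

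Between the mutants, 753 genes were higher in Y541S N cells and 912 lower than in D542G N cells, 1665 in all. Krt5 was at 300 ± 140 against 2350 ± 100 CPM (−2.96 ± 0.56, adjusted p = 0.0036), Krt10 at 13.6 ± 15 against 375 ± 220 CPM, Ltf lower by 3.42 and the immediate early gene Nr4a1 at 526 ± 24 against 1700 ± 250 CPM. Pgr was at 147 ± 30 against 38.2 ± 6.1 CPM (1.95 ± 0.29, adjusted p = 7.76e-04), Penk higher by 4.85 and fibronectin (Fn1) by 3.95. Endothelial markers were lower in 10 of 12 (camera adjusted p = 8.25e-11, adjusted p = 0.28 with an estimated correlation), with Cldn5 down by 2.43, and pericyte markers in 4 of 8, with Rgs5 down by 2.45. Squamous genes were lower in 4 of 15 (7 adjusted over the list alone). The count was 921, 869 and 556 without D542G 1, 2 and 3, 484 without Y541S 1, and 2537 in DESeq2. With Y541S number 3 alone it was 82, and each of the calls named ended.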

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

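The comparisons of giredestrant effects between genotypes were planned, as were the splits of the libraries and the test of milk gene ratios, and the other tests of explanations below were chosen after the results they measure had been seen.

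In ML cells the giredestrant effect differed from WT in 1129 genes in D542G, by a test of the difference itself. Among the largest were Spink8 (8.38), Krt6a (5.67), Kcnk16 (−7.61) and Sv2c (−5.76). WT giredestrant ML libraries had Spink8 and Saa1 at 0, so the fitted sizes of both rest on the prior count and set no bound. The Spink8 call ended without any 1 of 11 libraries of 12 (adjusted p 0.0504 to 0.0977), whereas Krt6a, Kcnk16 and Sv2c kept theirs in all 12. In Y541S ML cells 994 genes differed, led by Saa1 (9.22), Spink8 (8.85), Nrxn3 (−8.63) and Kcnk16 (−8.18). Saa1 ended without WT vehicle number 1 (0.054), WT giredestrant 1 (0.0644) or 2 (0.0586), or Y541S giredestrant 1 (0.0704). Spink8 ended without WT vehicle 1 (0.0615) or 3 (0.0529), Y541S vehicle 3 (0.0525), any WT giredestrant library (0.0594 to 0.0715) or Y541S giredestrant 1 (0.0755). Of 40 splits of the libraries, 1 (the real one) called as many genes as the D542G comparison, with 758 in the highest other. For Y541S 2 of 40 did, with 1000 in the highest other. The splits exchanged genotype labels within a treatment. They therefore test for any genotype difference and cannot single out a difference of effects, so chance is not excluded in either mutant.

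In Basal cells 108 genes differed in D542G, among them Gpx3 (4.88), Tnc (4.49), Lamp5 (−8.02) and Col9a1 (−4.12). Gpx3 ended without any 1 of 6 libraries (adjusted p 0.0576 to 0.0842). Tnc, Lamp5 and Col9a1 ended without any 1 of the same 8 (0.0576 to 0.108 for Lamp5 and Col9a1), namely WT and D542G vehicle 2 and 3, WT giredestrant 1 and 3 and D542G giredestrant 1 and 2. The 6 of Gpx3 are these without WT giredestrant 3 and D542G giredestrant 1. Of 40 splits, 2 called as many as 108, with 262 in the highest other, so chance cannot be excluded. In Y541S 766 genes differed, among them Krt6a (4.71), Gpx3 (4.66), Prtn3 (−3.18) and Fam180a (−2.3). Fam180a ended without any 1 of 9 libraries, all but WT vehicle 2, Y541S vehicle 1 and WT giredestrant 3 (0.051 to 0.129). The other 3 held in all 12, and ended with Y541S giredestrant numbers 1 and 2 both left out (0.147 to 0.173). Only 1 of 40 splits reached 766, with 71 in the highest other. These splits also exchanged genotype labels within a treatment, so chance in the difference of effects is not excluded.

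In 2 of 16 checks, of 4 measures in 4 groups of 6 libraries, 1 library stood apart by Dixon's criterion, which flags about 1 in 20 by chance. D542G giredestrant ML number 1 had an LP score of −1.3, against 1.29 to 2.6 in the other 5, but that score is 1 gene, Mmp3. Y541S giredestrant N number 2 had Esr1 at 397 CPM.

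Where 3 libraries faced 3, 10 splits are too few to give a share under 0.05. The real split was 1 of 10 to reach its count in each case, and the counts and highest others were as follows. Giredestrant in ML gave 5864 and 1 (WT), 3546 and 1 (D542G) and 4282 and 55 (Y541S), and in Basal 1901 and 2, 4849 and 0, and 2594 and 1. Against WT with vehicle, ML gave 3370 and 0 (D542G) and 1867 and 0 (Y541S), and Basal 10 and 0 and 27 and 0. With giredestrant, ML gave 447 and 10 and 2599 and 84, Basal 853 and 12 and 2397 and 0, and LP 5 and 0 and 587 and 0. N between mutants gave 1665 and 0. For N against ML, LP and Basal, 1 of 40 splits reached 5456, 6644 and 8148, with 2403, 1759 and 3789 in the highest others. This share is under 0.05, but it is the smallest that 40 splits allow and was not adjusted over the comparisons.

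N libraries held luminal and basal genes together. A mixture of ML and Basal cells is argued against, because Krt5, Krt14 and Trp63 needed a median Basal share of 65.4% (20 to 108.8), the 100 Basal signature genes 3.3% (1.4 to 6.9) and contractile genes 0.4% (0 to 1). A few genes taking most counts is argued against too, with 4.88% of counts in the 10 largest genes (4.01 to 7.33), inside the range of the other 18 libraries (3.85 to 7.42). Skin or nipple epithelium next to ML cells could contribute, since pan-luminal genes had a median log2 ratio to ML of −1.1 in D542G and −0.4 in Y541S, although Esr1 was higher by 1.57 and 1.44. The mutant receptor under giredestrant as the origin of such cells stays open and untested, as WT had no N library.

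Milk genes were high in Y541S giredestrant libraries 1 and 2 of all 4 populations and low in number 3. Depth is argued against, as number 3 was the shallowest in 2 of 4 populations. Milk RNA from 1 source, carried into each population, may explain the pattern, since within numbers 1 and 2 the ratios of Csn1s1 and Csn1s2a to Csn2 differed by at most 0.76 (log2) between populations, where under 1 had been predicted. In number 3, where milk genes were low, they ranged more widely, from −0.93 to 0.85 and from −4.17 to −3.06. Secretion by cells of every population would also keep such ratios and stays open, and no biological explanation was tested.

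Fibroblast genes were higher in Y541S than in WT LP cells. Fibroblast RNA in the gate may explain it, since 12 of 12 markers were highest in library 1 (1.35 ± 0.23 above the other 2, log2), which had Col1a1 at 2860, Col3a1 at 5530 and Acta2 at 2400 CPM. All 12 passed the low count filter in LP libraries, 0 of them are on another list, and the markers of the gate are not given in the sources used here. That test replaced an earlier one after values per library had been seen, namely that markers move alike between genotypes (11 of 12 called, mean 3.92, SD 0.64). Luminal cells that lose epithelial genes as they gain mesenchymal ones stay open, because pan-luminal genes went both ways (median −0.17, −0.71 to 0.34) and their high levels would hide a fall in a small share of cells. A difference of genotype stays open and untested.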

How the results depend on the processing

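The alternatives were planned, except for the joint luminal score and the fits without Y541S giredestrant numbers 1 and 2, which are tests chosen after the data had been seen. Counts that moved by more than 1.5 times are given by setting, with giredestrant effects first; the cause was not tested in any case.

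In DESeq2, giredestrant changed 2874 genes in WT Basal cells (1901 in edgeR). Mutants against WT gave 1314 in D542G ML cells with giredestrant (447), 241 and 679 in D542G and Y541S Basal cells with vehicle (10 and 27), 1766 in D542G Basal cells with giredestrant (853), and 735 and 1900 in D542G and Y541S LP cells (5 and 587). Differences of effects gave 2111 and 1891 in ML (1129 and 994) and 898 and 1602 in Basal cells (108 and 766), and Y541S against D542G N cells 2537 (1665). The share of higher genes went from 90 to 60.2% in D542G and from 70.4 to 56.7% in Y541S Basal cells with vehicle, from 38 to 48.7% for the difference in D542G Basal cells, and from 100 to 72.4% in D542G LP cells. In the fit of all 51 libraries the last 2 shares were 58.5 and 42.7%, so that their direction turned. That fit gave 69.9 and 66.7% in D542G and Y541S Basal cells with giredestrant (50.9 and 54.4) and 57.1% in Y541S LP cells (68.5). Without the filter these 5 shares were 51.1, 77.6, 61.2, 65.6 and 78.6%, and that of D542G Basal cells with vehicle 72%. The size factors of DESeq2 in edgeR moved 1 count, Y541S Basal cells with vehicle (82), and shifted no median log2 ratio by over 0.04. Without a low count filter D542G and Y541S Basal cells with vehicle gave 50 and 158, the difference in D542G Basal cells 223 and D542G LP cells 107. In 1 fit of all 51 libraries the counts were 753 in D542G ML cells with giredestrant, 32 and 71 in Basal cells with vehicle, and 1310 and 2657 in LP cells. D542G alone called 4578 genes between N and Basal cells (8148), and 562 higher and 466 lower in N than in all others (1128 and 940). Y541S alone called 2153 and 4023 between N and ML or LP cells (5456 and 6644), and 490 and 414. Pdgfrb changed direction between N and LP cells in D542G alone (0.20), and Procr in Y541S alone (−0.18).

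Same-numbered libraries were not taken as pairs. Their deviations correlated above 0.1 in 28 of 36 pairs in the N fit (median 0.18), namely 18 of 18 in Y541S (0.19 to 0.45) and 10 of 18 in D542G, 4 of 45 in ML, 6 of 45 in Basal and 4 of 9 in LP. In the N fit 24 of 24 libraries correlated best with their own number, 21 in every cell type, a hint from the data and not the design. With the replicate block D542G and Y541S gave 4 and 14 in Basal cells with vehicle, and 0 and 278 in LP cells. N between mutants gave 769 (234 higher and 535 lower). Only these moved by over 1.5 times. They compare animals of different genotypes, so cannot test pairing. The 0 is from edgeR, where 2677 genes had unadjusted p under 0.05 without the block.

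With 1 library left out, the lowest and highest counts of the giredestrant effect were 4244 and 6086 in WT ML cells, 1176 and 3160 in D542G, and 2395 and 3912 in Y541S, and in Basal cells 493 and 2429, 2135 and 4776, and 1037 and 2076. For mutants with vehicle they were 1907 and 2532 (D542G ML), 648 and 2017 (Y541S ML), 0 and 18 (D542G Basal) and 0 and 100 (Y541S Basal). With giredestrant they were 103 and 450 (D542G ML), 912 and 2783 (Y541S ML), 166 and 840 (D542G Basal), 1189 and 2407 (Y541S Basal), 0 and 42 (D542G LP) and 0 and 979 (Y541S LP). Differences of effects gave 463 and 1253 (D542G ML), 518 and 1145 (Y541S ML), 3 and 609 (D542G Basal) and 278 and 1095 (Y541S Basal), and N between mutants 484 and 1681. Each 0 is from edgeR. In Basal cells it came without WT vehicle 2 (both mutants), D542G vehicle 1 or 2, or Y541S vehicle 1 or 2, and in LP cells without WT giredestrant 1 or 3 (both mutants) or D542G giredestrant 1. With all libraries 1650, 2529, 2677 and 3677 genes had an unadjusted p under 0.05 and DESeq2 called 241, 679, 735 and 1900. N against ML, LP and Basal kept within 1.5 times. Of 9150 values of named genes with 1 library left out, 6791 kept their call or its absence, 2357 lost it, 2 gained it and 0 changed direction.

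Without Y541S giredestrant numbers 1 and 2 the lone library left was assumed to vary like the other groups. The counts were 1238 (giredestrant, ML), 125 (against WT, ML), 167 (difference, ML), 121, 121 and 67 in Basal cells, 0 in LP cells (edgeR; 3677 at an unadjusted p under 0.05 and 1900 in DESeq2 with all libraries), 1971, 2641 and 4693 for N against ML, LP and Basal, and 82 between N cells. Genes higher and lower in N than in all others were 314 and 329. Changes of direction were Csn2 (−1.53), Csn1s2a (−3.37) and Csn1s1 (−0.16) under giredestrant in ML, Hsd11b2 (−0.95) and Fkbp5 (−0.11) against WT in ML, and Csn1s2a (−1.05) under giredestrant in Basal cells.

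Of 528 list tests 221 were called, and 5 with an estimated correlation. These were receptor targets and progenitor markers in N against ML and LP, and squamous genes in N against LP. The size factors of DESeq2 ended 4 list calls, adipocyte markers in Y541S ML cells with vehicle (0.059), immune markers in D542G Basal cells under giredestrant (0.062) and transition factors in N against Basal (0.0503) and between N cells (0.0529). The ML score, 0.12 higher in N than in ML with its 1 gene, was lower with the joint luminal score (−1.29). With 50 or 200 signature genes the Basal score kept its direction (−3.75 and −3.23), and the ML and LP scores, of 1 gene each, could not change.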

Other observations

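The genes in the next 2 paragraphs, and the libraries after them, were singled out after their values had been seen, and no further tests were run on them beyond the planned comparisons of N.

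Several genes that the report leaves out were higher in N cells than in each of the other 3 populations (n = 6 libraries a population). The cornified envelope and growth arrest gene Dapl1 was at 122 ± 51 CPM against 10.7 ± 8.3 in ML, 1.41 ± 0.8 in LP and 6.42 ± 3.9 in Basal cells (log2 ratio to ML 3.76, adjusted p = 2.10e-06). Ppp1r14c, an inhibitor of protein phosphatase 1, was at 41.1 ± 14 CPM (4.16, adjusted p = 4.43e-08), and the gluconeogenic enzyme gene Fbp1 at 87.3 ± 61 CPM against at most 5.11 ± 3.8 elsewhere. The peptidylarginine deiminase gene Padi3, which acts in hair follicles, was at 44.3 ± 26 CPM against 4.74 ± 2.7 in ML. The lysophosphatidic acid receptor gene Lpar3 was at 68.2 ± 23 CPM against 4.28 ± 0.99, 1.89 ± 0.9 and 8.23 ± 2.4 CPM in ML, LP and Basal cells.

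Other genes were lower in N than in each of the other 3. Lcn2 was at 130 ± 29 CPM against 845 ± 440 in ML, 1170 ± 340 in LP and 841 ± 270 in Basal cells (−2.54 against ML, adjusted p = 1.08e-08), and complement C3 at 122 ± 80 CPM against 613 ± 270, 945 ± 560 and 887 ± 370. The adhesion receptor Adgrl3 was at 6.62 ± 1.7 CPM against 46.6 ± 17 or more, and Pdlim3, which binds alpha-actinin, at 43 ± 9.8 against 215 ± 110, 392 ± 130 and 893 ± 140 CPM.

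The libraries of Y541S with giredestrant were unlike each other in a receptor target as well as in milk genes. Greb1 was at 35.4, 13.9 and 4.07 CPM in ML and at 189, 90.2 and 13.4 CPM in N libraries 1 to 3, in the order of Csn2 in ML (11400, 3470 and 27.8 CPM) and in N (2930, 764 and 7.97 CPM). Whether these animals received or absorbed the same dose is not given in the sources used here.

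Single libraries of other groups also stood apart. D542G giredestrant ML number 3 had Csn2 at 844 CPM against 2.31 and 45.9 in the others, and D542G giredestrant LP number 3 had Col1a1 at 597 CPM against 80.7 and 70.4.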
